A study of Mus musculus with 47 samples.

How the data were processed

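Total RNA was extracted with Trizol, per the labels' protocols, and small RNAs were sequenced in 6 pools of barcoded libraries. The files deposited by the authors hold unsplit sequencing reads of the 6 pools, with no tally and no normalization. The aligner, genome build and barcode sequences used by the authors are not given in the sources used here. A read holds the reverse complement of a small RNA, a linker of 6 bases and a barcode of 6 bases, as read from the sequences themselves.

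Reads were assigned to 10 barcode sequences by exact match after the linker, for inserts of 17 to 24 nucleotides. Longer inserts, which the plan had allowed, do not leave room for a full barcode. An exact barcode was found in 35.0% of 1138501 reads in pool 1, 48.7% of 2142056 in pool 2, 11.4% of 2737747 in pool 3, 7.22% of 3362208 in pool 4, 49.6% of 777575 in pool 5 and 33.7% of 1250788 in pool 6. Inserts were matched exactly to 1174 microRNA hairpins of GENCODE M21 (GRCm38), with the arms counted apart. Inserts shared by several names were kept under the joint name. Close relatives such as the let-7 members differ by few bases, so read errors can move counts between them.

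The labels name a barcode for each sample but give no sequence for it, and no library was tied to a sample. Pool 6 held 8 barcodes for its 8 listed samples and lacked TACATG and TAGCAT. The names that pool 6 does not use are 1-month cerebellum in pool 4 and P6 cerebellum in pool 5. If pool 6 holds only its listed samples, TACATG and TAGCAT stand for those tissues there. The labels do not tell which name is which, and this was not used. Tissue was never taken from the values. Pools 1 and 2 held 9 and 10 barcodes in quantity where 4 and 5 samples are listed. The 10 libraries beyond the listed ones could not be told from the others, and neither pool was used per library. In pools 3 and 4, 9 barcodes were found where 10 samples are listed. Pools 3 and 4 shared a flow cell, and pools 5 and 6 were run on others.

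The planned tests were limma-voom fits between groups and set tests on the lists. Without groups they could not be run. The 23 microRNA lists, the minimum of 10000 microRNA reads, the filter of 10 CPM in 4 libraries and the median-of-ratios scaling were fixed before the data were examined. The pool comparisons, the pseudocount of 50 CPM, the rule for a call and all alternatives as applied to them were chosen after pool medians and values per library had been seen. Counts were scaled over 54 arms found in all 29 used libraries. A call required non-overlapping ranges, with 1 library of pool 4 and 2 of pool 5 allowed out of range where the labels put that many samples of another tissue in the pool, and a difference of log2(median + 50) of at least 1. Named microRNAs were the 10 with the largest rise and fall among calls of at least 100 CPM, plus 6 members of miR-17~92 fixed beforehand. The planned rule used adjusted p-values in place of the call. Members used as examples of a list were picked from the calls, and miR-338-3p was chosen after its values were seen.

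List medians were set against 10000 random lists matched on mean level. Whole-pool totals were counted from the first 18 bases of each read without linker or barcode, which weights libraries by yield. Random reassignment of libraries to pools was drawn 100 times freely and 100 times within barcodes. The rule was tested on simulated counts for pool 4 against pools 3 and 5, with 379 arms and 80 of them changed. It recovered 57.5% of 4-fold and 82.5% of 8-fold changes and made 0 other calls. The simulated libraries varied with a dispersion of 0.159, and 1 library of pool 4 was left unchanged, as many as the rule allows. Changed arms were drawn from those of at least 100 CPM on average. Pools 3 and 5 were not mixed tissues, and no effect of pool, flow cell or barcode was simulated. These shares therefore do not describe fainter arms or arms that vary more within a pool, and the 0 other calls do not cover such effects. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Scaling, filter, matching, barcode, linker, insert length, pseudocount, depth minimum and libraries were varied in 14 alternatives and by leaving out each library.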

Results

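Small RNAs were sequenced from 47 mouse samples in 11 groups of tissue and genotype. Purified cerebellar granule neuron progenitors, the cells from which this form of medulloblastoma arises, came from pups at postnatal day 6 (P6). There were 4 wild-type samples, 5 lacking p53 and Ink4c, and 5 heterozygous for Ptc and lacking Ink4c. Whole cerebellum at P6 was sampled in the same numbers. Whole cerebellum at 1 month gave 3, 4 and 2 samples of these genotypes. Purified medulloblastoma cells gave 5 samples from each of the mutant genotypes. The samples were sequenced as 6 barcoded pools, and the sources used here do not tie a barcode sequence to a sample name. Each library could therefore be placed in a pool but not in a group of tissue and genotype. By elimination the tissue, but not the genotype, of libraries with TACATG and TAGCAT in pools 4 and 5 would follow. That requires pool 6 to hold only its listed samples, and it was not used. None of the 16 planned comparisons of groups, such as tumour against progenitor or mutant against wild type, was made. What follows compares pools whose listed samples the labels give. Which of the listed samples are among the libraries used is not known where some were missing or set aside.

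Pool 3 held 5 tumour and 5 P6 cerebellum samples, and pool 4 held 9 cerebellum samples of 1 month and 1 of P6. Pool 5 held 8 P6 cerebellum samples, 1 progenitor sample and 1 tumour sample. Pool 6 held 4 progenitor and 4 tumour samples and no whole tissue. After libraries under 10000 microRNA reads were set aside, 6, 8, 7 and 8 libraries remained in pools 3 to 6. In pools 3 and 4, 9 libraries were found for 10 listed samples. The shares of each tissue among the used libraries of pools 3, 4 and 5 are therefore not known. Whether the samples of another tissue in pools 4 and 5 are among them is not known either. The 36 libraries found in quantity in these pools had 2922 to 69787 microRNA reads each. MicroRNAs made up 74.7% to 81.4% of inserts in pool 3, 71.7% to 76.5% in pool 4, 17.5% to 65.4% in pool 5 and 50.5% to 76.0% in pool 6. At such depth values near 50 CPM rest on few reads and carry large counting error. Values are medians and ranges over libraries in scaled CPM, which are reads per library total divided by a median-of-ratios factor, so that values of a library need not add up to a fixed total. Medians and ranges are given because libraries without a known group are not replicates, and no p-value is given between pools.

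The first comparison set pool 4, mostly mature cerebellum, against pools 3 and 5, which hold P6 cerebellum, tumour cells and 1 progenitor sample. In pool 4, microRNAs of the miR-17~92 cluster and its paralogs, which are known to promote proliferation, were far lower than in pools 3 and 5. Median miR-20a-5p was 645 CPM in pool 4 (range 92.3 to 18878, 8 libraries), 28606 in pool 3 (17874 to 64845, 6 libraries) and 53406 in pool 5 (17422 to 97364, 7 libraries). Of 17 neuronal microRNAs 4 were higher and 2 lower, and the most abundant of the higher ones was miR-124a-3p, at 204300 CPM (37875 to 415658) against 22710 (9032 to 51501) and 33342 (26102 to 192980). Of 379 microRNA arms, 14 were higher and 24 lower in pool 4 than in both other pools. A call required a median difference of at least 1 on the log2 scale and library ranges that did not overlap, allowing for the 1 sample of pool 4 and the 2 samples of pool 5 of another tissue. Random reassignment of libraries to pools of these sizes gave 0.31 calls on average, or 0.082% of the arms, and at most 6 in 100 draws. Drawn within barcodes, the highest count was 12. Both kinds of draw mix libraries across pools, so they cannot tell a difference of tissue from one of pool or flow cell. This holds for every comparison below as well, and the rule was chosen after values had been seen.

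Of the 12 measured members of the miR-17~92 list, 9 were lower in pool 4 and none was higher. The median log2 difference over the list was -3.50 against pool 3 and -3.72 against pool 5. Both medians lay below nearly all of 10000 random lists matched on abundance, at percentiles 0.00 and 0.04. The random lists drew arms independently, whereas several members share a host gene, as given below. The percentiles can therefore overstate how unusual the list is. For miR-17-5p the log2 difference was -5.53 against pool 3 and -7.11 against pool 5, for miR-18a-5p it was -4.36 and -5.14, and for miR-92a-3p it was -3.50 and -1.61. The values of miR-19a-3p were -2.67 and -3.68, and those of miR-19b-3p were -3.49 and -3.76. The hairpins of miR-17, miR-18a, miR-19a, miR-20a, miR-19b-1 and miR-92a-1 lie in exons of the noncoding gene Mir17hg on chromosome 14 (GRCm38). The first of them starts at 115043671 and the last ends at 115044506. The paralogs miR-106b-5p, miR-93-5p and miR-25-3p, whose hairpins lie within Mcm7, a gene of DNA replication licensing on chromosome 5, differed by -3.36, -4.26 and -3.65 against pool 3. Whole-pool totals, counted without linker or barcode, gave differences of -2.44 for miR-17-5p and -2.52 for miR-20a-5p against pool 3. Against pool 5 they gave -2.74 for miR-17-5p, -2.89 for miR-20a-5p, -3.21 for miR-18a-5p, -3.80 for miR-19b-3p and -1.71 for miR-92a-3p. The sizes for miR-17-5p, miR-20a-5p and miR-18a-5p were thus smaller in whole-pool totals. Those totals also weight libraries by yield in place of a median over libraries. The highest pool 4 library had 18878 CPM of miR-20a-5p against a median of 645. The smaller sizes therefore cannot be put down to linker and barcode alone.

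**Figure D1:**
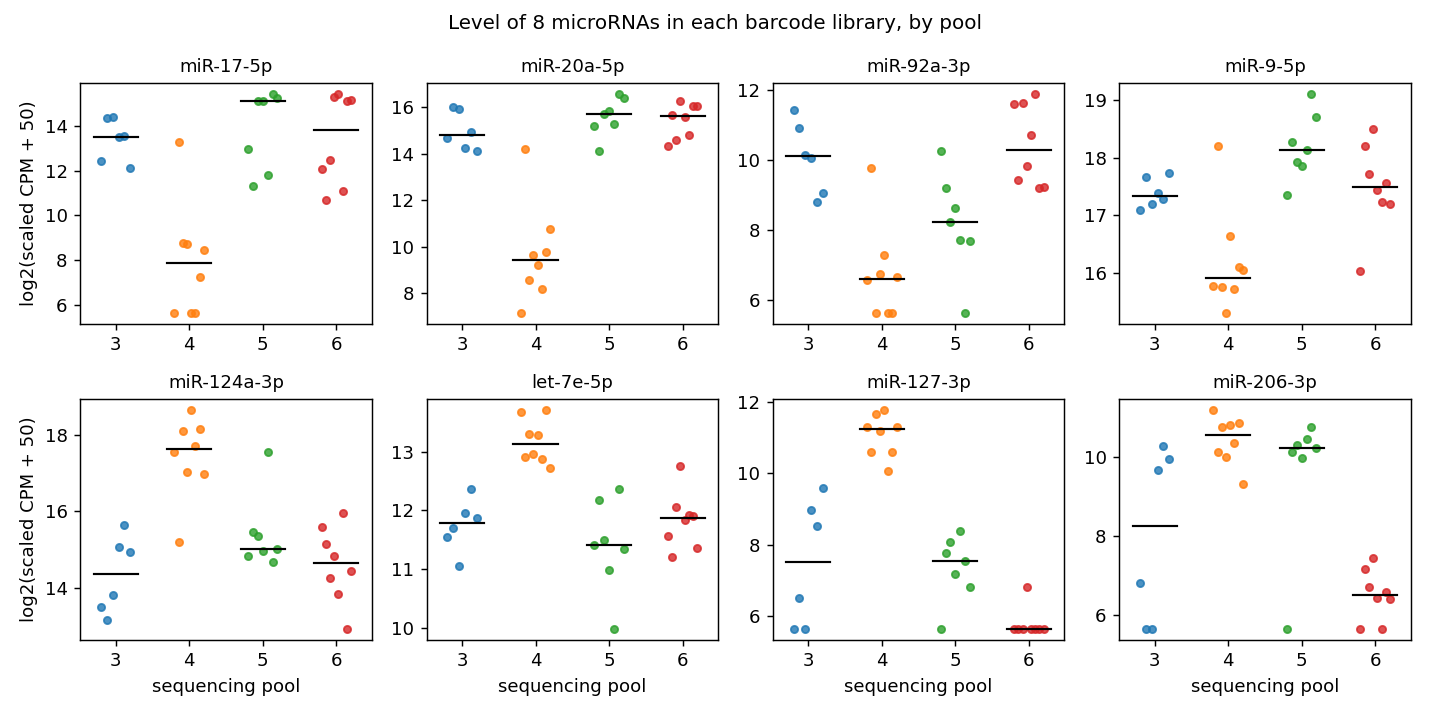
Level of 8 microRNAs in each used barcode library (points) of pools 3 to 6 on a log2(scaled CPM + 50) axis, with the pool median as a bar. miR-20a-5p has a median of 645 CPM in pool 4 and at least 28606 in the other 3 pools, and miR-127-3p has a median of 2372 CPM in pool 4 and 0 in pool 6.

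Among 17 measured members of the neuronal differentiation list, 4 were higher in pool 4 and 2 were lower. The higher members were miR-124a-3p, miR-129-5p, miR-132-5p and the reads shared by both miR-128 hairpins. Of these, miR-132-5p rests on few reads, with a median of 77.4 CPM in pool 4 (0 to 164) and 0 in pools 3 and 5. Reads of the miR-128-3p name alone, with 2.54 and 6.29, did not meet the rule on ranges. The shared reads, from hairpins in introns of R3hdm1 and Arpp21, had log2 differences of 2.46 against pool 3 and 4.98 against pool 5. Without any one of 3 pool 3 libraries the difference against pool 3 was 3.52 to 3.55. Without any one of the others it was smaller than 2.46, by less than the spread between libraries. For miR-129-5p the differences were 3.48 and 3.96. The other 11 members were not called, among them miR-125b-5p with -0.50 and 0.32. The lower members were miR-9-5p, with -1.41 and -2.21, and miR-135a-5p, with -2.15 and -2.26. In whole-pool totals, which also weight libraries by yield, miR-9-5p differed by -0.15 against pool 3, so its difference there was not held in them. The list counts 1 arm per member. The arm of miR-9 that it leaves out, miR-9-3p, was called lower in pool 4, with -1.90 and -8.11. In whole-pool totals miR-9-3p had -1.54 and -4.16.

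From the imprinted Dlk1-Dio3 cluster on chromosome 12, 34 members were measured, 4 were higher in pool 4 and none was lower. Median miR-127-3p was 2372 CPM in pool 4 (1020 to 3476), 181 in pool 3 (0 to 722) and 138 in pool 5 (0 to 280). Its log2 difference against pool 3 was 3.39, and 4.72 to 4.77 without any one of 3 pool 3 libraries, since the 6 libraries lay apart in this arm. Without any one of the others the difference was smaller than 3.39, by less than the spread between libraries. Its hairpin lies between genes of its strand at 109592846 to 109592915. The let-7 family, regulators of developmental timing, had 9 measured members, of which let-7e-5p was higher in pool 4, with log2 differences of 1.35 and 1.72. The list median against pool 3 was 0.10, but in whole-pool totals all 9 members were above 0 there, from 0.23 for miR-98-5p to 2.17 for let-7e-5p. Of 3 measured miR-29 members, miR-29b-3p was higher, with 2.39 and 4.14. Of 5 measured members of the choroid plexus and ependyma list 1 was higher, miR-204-5p, with 2.89 and 4.12. The other 4 had negative differences and were not called, such as miR-449a-5p with -3.39 and -4.72, and the list medians were -0.53 and -1.63. The oligodendrocyte microRNA miR-338-3p, in an intron of Aatk, had a median of 3305 CPM in pool 4 (476 to 29868) against 457 in pool 3 (0 to 1507) and was not called. The miR-130 and miR-301 family had 2 of 4 members lower in pool 4, miR-130a-3p and miR-130b-3p.

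**Figure D2:**
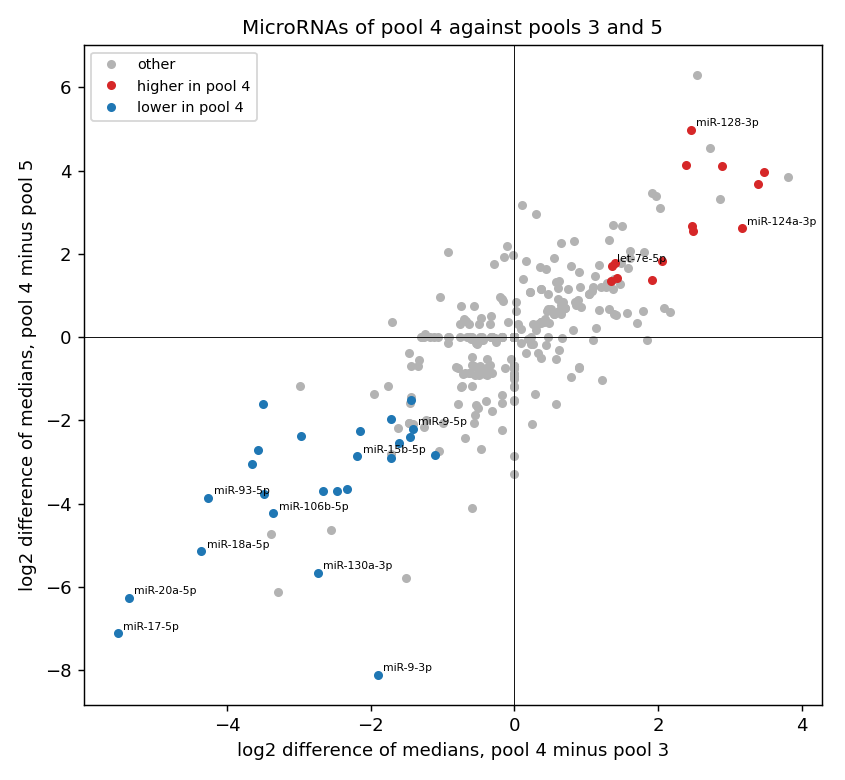
Log2 difference of pool medians for each of 379 microRNA arms, pool 4 minus pool 3 on the horizontal axis and pool 4 minus pool 5 on the vertical axis. The 14 arms called higher in pool 4 are red and the 24 called lower are blue. The point of miR-17-5p lies at -5.53 and -7.11, against -2.44 and -2.74 in whole-pool totals.

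Whole-pool totals had the same sign against both pools for 14 of the 14 higher arms and 22 of the 24 lower ones, the exceptions being miR-340-5p and miR-374b-5p, and a size of at least 1 for 14 and 18 of them. Upper-quartile scaling gave 9 higher and 25 lower arms, differences between libraries of the same barcode gave 30 and 32, keeping libraries of low depth left 6 higher ones, and leaving out the pool 4 library with barcode GTTACA raised them to 22.

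The second comparison set purified progenitor and tumour cells against whole cerebellum. The arms that stood apart from both whole-tissue pools were mostly lower in pool 6. Of the skeletal muscle list, miR-206-3p had a median of 40.7 CPM in pool 6 (0 to 124, 8 libraries), against 1476 in pool 4 (583 to 2307) and 1153 in pool 5 (0 to 1703). The other measured member of that list, miR-1a-3p, had medians of only 40.2 CPM in pool 4 and 40.1 in pool 5. So miR-206-3p is not read as a sign of muscle here. Neuronal miR-218-5p, from introns of Slit2 and Slit3, had 237 CPM (46.4 to 559) against 3407 and 2324. Lower than in both whole-tissue pools were 5 arms, miR-206-3p, miR-218-5p, miR-138-5p, miR-127-3p and miR-136-5p. Against pool 5, miR-138-5p, miR-127-3p and miR-136-5p rest on few reads. Their medians there were 80.1, 138 and 188 CPM, with minima of 0, and their medians in pool 6 were 0. Called higher was 1 arm, miR-17-3p. Its median was 1052 CPM (504 to 1614) against 65.3 in pool 4 and 249 in pool 5. The other arm, miR-17-5p, had -0.76 against pool 5 but 0.84 in whole-pool totals, so its direction there is not settled. None of the 12 miR-17~92 members was called, with a list median of -0.36 against pool 5. Random reassignment gave 0.01 calls on average and at most 1. Same-barcode differences gave 4 higher and 11 lower arms. As tissues were spread unevenly over pools that were sequenced apart, pool and tissue cannot be separated here.

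The third comparison set the same purified cells against the mature tissue of pool 4. In pool 6, 23 arms were higher and 37 lower, against 0.17 calls on average and at most 3 in random reassignments, or at most 11 when drawn within barcodes. Same-barcode differences gave 48 higher and 52 lower arms, and whole-pool totals kept a size of at least 1 for 21 of the 23 and 32 of the 37. From the miR-17~92 list 6 of 12 members were higher and none lower, with a list median of 3.52 on the log2 scale. The difference was 6.35 for miR-17-5p and 6.18 for miR-20a-5p, and 3.58 and 3.29 in whole-pool totals, where miR-92a-3p had 3.70. Of the Dlk1-Dio3 members 13 of 34 were lower and none higher, and miR-127-3p had a difference of -5.60. The neuronal list, which counts 1 arm per member, had 7 of 17 members lower and none higher, with differences of -2.99 for miR-124a-3p, -5.13 for miR-129-5p and -4.07 for miR-138-5p. The arm of its member miR-9 that the list leaves out, miR-9-3p, went the other way. It was called higher in pool 6, by 5.11 and by 3.39 in whole-pool totals. Lists of other cell types went different ways. In the oligodendrocyte, smooth muscle and skeletal muscle lists 1 of 2 measured members each was lower. These were miR-338-3p with -4.63, miR-143-3p with -3.23 and miR-206-3p with -4.07. No arm of the endothelium, erythroid or leukocyte lists was called, such as miR-126a-3p with -0.18 and miR-142a-5p with 1.34. The choroid plexus and ependyma list had a median of 1.47, and 1 of its 5 measured members was higher, miR-34c-5p. It was higher by 3.44, from 106 CPM to 1639, but by 1.40 in whole-pool totals. Among the other arms, miR-378a-3p, in an intron of the mitochondrial regulator Ppargc1b, differed by -2.59. Higher in pool 6 were also miR-130a-3p and miR-191-5p, which were low in both pools of the flow cell that held pool 4. So was miR-9-3p, with medians of 137 and 0 CPM in pools 3 and 4, 13718 in pool 5 and 1673 in pool 6.

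Tumour and progenitor samples lay side by side in pool 6, and the range over its 8 libraries bounds the measured values only, since a difference between barcodes can hide or offset one between tissues. Levels of miR-20a-5p ran from 20556 to 78085 CPM, a span of 1.92 on the log2 scale. The span was 1.63 for miR-93-5p, 2.69 for miR-92a-3p, 2.95 for miR-18a-5p and 3.11 for miR-19a-3p. For miR-106b-5p and miR-19b-3p it was 5.18 and 5.87. For miR-17-5p it was 4.76, from 1576 to 44010 CPM.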

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

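Both results here were found after the barcodes had been tallied, and no explanation was tested for them. Pool 1 held 5 barcodes in quantity beyond its 4 listed samples, and pool 2 held 5 beyond its 5 listed samples. The least read of the 9 barcodes in pool 1 had 24273 reads, against 48 for the barcode that was not in quantity. In pool 2 the 10 barcodes had 19052 to 163763 reads. These libraries were not analysed here, and no library lay in a known group, so outlying samples within groups were not sought.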

How the results depend on the processing

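All alternatives were applied to comparisons chosen after the data were seen. No paired analysis was possible because no library carries a sample's replicate number, and a shared barcode matches libraries technically, not by animal. The planned limma-voom, limma-trend, quality-weight, count-model, pool-covariate and set-test fits were not run for want of groups. Arms higher in pool 4 than in pools 3 and 5 numbered 14. They were 9 with upper-quartile scaling, 25 with 1 barcode mismatch, 6 with low-depth libraries kept and 30 from same-barcode differences. Arms higher in pool 6 than in pools 4 and 5 numbered 1, and were 3 with quantile normalization, 2 with 1 barcode mismatch, 2 with low-depth libraries and 4 from same-barcode differences. The 5 lower ones were 3 with low-depth libraries and 11 from same-barcode differences. The 23 arms higher in pool 6 than in pool 4 were 48 from same-barcode differences. Causes were not tested. Leaving out 1 library gave 14 to 22 higher and 24 to 29 lower in pool 4, 1 to 3 higher and 5 to 7 lower in pool 6 against both pools, and 22 to 26 higher and 36 to 40 lower against pool 4. Of named microRNAs called in pool 4 against pools 3 and 5, none changed sign against pool 3 under any alternative run. The call already requires separate ranges, which fixes that sign under another pseudocount and nearly so when 1 library is left out. For those settings the kept sign is therefore no added support. Sizes did move: of 33 named values against pool 3, 8 moved by more than the spread between libraries without any one of the pool 3 libraries TACATG, TATACG or TTACAG (miR-127-3p, both miR-128-3p names, miR-138-5p, miR-206-3p, miR-218-5p, miR-300-3p and miR-381-3p, all to larger differences), 7 in whole-pool totals, 5 with a pseudocount of 1 or of 10, and 3 with low-depth libraries kept. Without any one of the other used pool 3 libraries, each of the 33 values moved by less than that spread, and the 8 named ones moved to smaller differences. Few microRNA reads per library limit values near 50 CPM.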

Other observations

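The tests below were chosen after the results were seen, except 4 whose measure had not been looked at: the let-7 totals without linker, the let-7 values with 1 mismatch, the correlation of miR-17-5p with depth, and the barcode shares over all abundant arms.

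Libraries within a pool fell apart in some microRNAs, and no tissue was assigned from this. In pool 3, which holds tumour cells and P6 cerebellum, among the 6 used libraries the endothelial microRNA miR-126a-3p was at 93.6, 162 and 407 CPM with barcodes GTAACT, GTTACA and TACAGT, and at 4657, 5752 and 4945 with TACATG, TATACG and TTACAG. In the same order miR-206-3p was at 62.4, 0, 0, 768, 1204 and 947 CPM. In pool 6, of progenitors and tumour cells, miR-29a-3p was at 92.7 CPM with ACGTTA, 270 with GTAACT, 341 with GTTACA, 288 with TACAGT, 2019 with ACAGTT, 6027 with TAGTCA, 12578 with TATACG and 10397 with TTACAG. In pool 4 the library with GTTACA had 18878 CPM of miR-20a-5p, against 92.3 to 1672 in the other 7, and 37875 CPM of miR-124a-3p against 129837 to 415658.

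The level of miR-17-5p differed between barcodes in pools 3, 5 and 6, from 1576 CPM with ACGTTA to 44010 with TACAGT in pool 6. Barcodes held 90.0% of its within-pool sum of squares over 27 libraries, 6 of them of low depth (permutation p = 2e-05), but it was picked for this difference, so that p decides nothing. For miR-20a-5p the share was 67.1% (permutation p = 0.016). Over all 142 arms of at least 100 CPM in the 21 used libraries, the median share between barcodes was 71.0%. It was at most 57.4% when barcodes were shuffled within pools, and 0 of 100 shuffles were as large. In these libraries miR-17-5p had 80.2%, and 39 arms, itself included, had at least that share. The barcode is parted from the microRNA in the read by the 6 linker bases. A bias of the barcoded linker toward some sequences is a candidate explanation. The labels also give tissues and genotypes in blocks along the barcode names in several pools, so the 0 of 100 shuffles over all abundant arms cannot tell a barcode in the linker from that layout. Depth stays open too, with a mean within-pool Spearman correlation of 0.465 (permutation p = 0.021, not adjusted), and tissue and genotype were not tested.

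The let-7 family was lower in pool 5 than in pool 3, by a median log2 difference of -2.03 over 9 members, although both pools hold P6 cerebellum. The microRNA share of inserts also differed, 74.7% to 81.4% in pool 3 against 17.5% to 65.4% in pool 5, and was not tested as a cause. Whole-pool totals without linker or barcode gave -1.48 and matching with 1 mismatch gave -1.29, which argues against misread linkers alone or read errors alone as the whole cause. Both together were not tested. Over all libraries found in quantity, summed let-7 ran from 311718 to 671485 CPM in 9 libraries of pool 3 and from 69944 to 317321 in 10 of pool 5, and 1 library of pool 3 lay within the range of pool 5. That overlap involved libraries of low depth. In the used libraries 0 of 6 in pool 3 lay within the range of the 7 in pool 5, both with the main scaling (lowest 366199 against highest 200299 CPM) and with library totals, although at least 1 of the 6 is P6 cerebellum by the labels. This argues against tissue make-up as the whole cause, and library preparation was not tested.

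Both miR-130a-3p and miR-191-5p were lower in pools 3 and 4, of one flow cell, than in pools 5 and 6, with log2 differences of -4.19 and -3.76. Medians of miR-9-3p were 137 and 0 CPM in pools 3 and 4 against 13718 and 1673 in pools 5 and 6, with overlapping ranges in pools 3 and 6, and it was not part of the tests. Whole-pool totals gave a median of -2.39 and matching with 1 mismatch gave -3.60, so neither misread linkers alone nor read errors alone may account for all of it. Both together were not tested. Linker misreads remain a candidate for part of the difference. Other effects of the flow cell or preparation stay open, and no biological explanation was tested.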
